A study of Mus musculus with 12 samples.

How the data were processed

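The 12 samples were total RNA of murine acute myeloid leukaemia cells, 4 arrays for each of 3 lines, grouped by the names in their labels. The sources used here describe biotin-labelled cRNA made by the array maker's standard protocol, and probe set names that end in PM point to a perfect-match design. The deposited values are intensities on a linear scale, made by the authors with MAS5 per the submitters' processing notes, which give no version. Scaling target, background correction and any filter are not given in the sources used here. The deposited intensities had no constant mean: the mean after trimming 2% of probe sets at each end was 80.9 to 83.0 on the TB13 arrays and 115.1 to 117.3 on the other 8. No column of another sample was present.

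Of 45141 probe sets, 104 control probe sets were left out of the tests. Gene names came from the platform annotation, in which 28898 of the other probe sets had 1 gene, 551 several and 15588 none. Only those with 1 gene were named and tested as genes, and no symbol changed when updated through gene identifiers of the mouse RefSeq table. The files name no genome build, and no coordinates are given. Probe sets were kept where they exceeded their array's median on at least 4 of the 12 arrays, which left 17480 with 1 gene. Each gene was represented by the probe set with the highest mean, giving 11223 genes.

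Analyses ran in R 4.3.3 with limma 3.58.1. Intensities were taken to log2(value + 12.7), where 12.7 is the 25th percentile of all values, so a log2 change understates the change of dim genes. No further normalization was applied in the main setting. All 12 arrays entered 1 linear model with 3 groups and moderated variances with a trend on mean expression. The contrasts were TB13 minus Trib1, TB14 minus Trib1, the mean of both lines minus Trib1 and TB14 minus TB13. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and calls of 2-fold or more were counted as well. The median SD of a gene within a line was 0.071 on the log2 scale. Arrays have no read depth, and their number limits the precision.

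Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, with Benjamini-Hochberg adjustment over the lists of a contrast. The 30 lists, fixed before the data were examined, held 628 genes, of which 445 were tested. A list needed 3 tested genes, and 1 list fell short. Apart from some monocyte genes given at the end of this paragraph, genes named in the text followed a rule fixed before the data were examined. It took the introduced genes, Spi1, Cebpa and the 3 study genes, and for both lines against Trib1 the 10 largest rises and 10 largest falls called in all 3 contrasts with Trib1 whose 8 values lay outside the range of the Trib1 arrays. It also took the 8 largest rises and falls of TB14 against TB13 with ranges that did not overlap, and up to 4 called members of each list plus members called in opposite directions in the lines. Names that are only clone identifiers were passed over. Outside the rule Adgre1, Ccl9, Lgals3, Mpeg1 and Ms4a6c, members of the monocyte list, were named after the results were seen.

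Alternatives fixed before the data were examined were quantile and median scaling, other filters and pseudocounts, other variance models, the replicate number as a block, other ways to treat the probe sets of a gene, line means, a 2-fold threshold, leaving out each array, and, for lists, medians against 10000 random lists matched on mean expression. Cyclic loess scaling, calibration on the hybridization controls, quantile scaling with a 2-fold threshold or with line means, and leaving out TB13 were added after the data were seen. The 5 scalings named in the text are the deposited values and 4 of these. Calibration fitted, for each array, the mean of the 18 hybridization controls over all arrays as a quadratic curve of that array's values, held constant outside their range.

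The code was tested on simulated data with the means and spreads of the 11223 genes. For both Bcl11a lines against Trib1, with 50 genes changed per fold size, 98% of changes of 1.2-fold and 100% of those of 1.5-fold, 2-fold and 4-fold were recovered, and 14 unchanged genes were called. Figures were drawn with matplotlib 3.10.9.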

Results

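Gene expression was measured on 12 oligonucleotide arrays hybridized with biotin-labelled cRNA from total RNA of murine acute myeloid leukaemia cells. The cells were grown with interleukin-3 and belonged to 3 lines with 4 arrays each. The line called Trib1 expressed Trib1 alone, a pseudokinase known to drive degradation of the transcription factor C/EBPalpha. The lines called TB13 and TB14 were labelled as expressing Trib1 together with Bcl11a, a zinc finger protein known as a transcriptional repressor. The series is concerned with whether Bcl11a acts against the transcriptional activity of PU.1, the myeloid transcription factor encoded by Spi1. Values were linear intensities of 45141 probe sets, and 11223 genes were tested. Within a line the arrays correlated across probe sets at 0.9938 or above, and nothing in the labels said that the 4 arrays came from separate cultures. The p-values therefore measured only the spread between arrays, which may be technical, and with a single Trib1 line they did not measure the spread between lines. The number of arrays limited the precision.

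The probe sets for the introduced genes stayed dim in every line. The 4 Bcl11a probe sets lay between 6.70 and 21.5 intensity units on all 12 arrays, near or below the array medians of 20.8 to 25.9. The 2 Trib1 probe sets lay between 14.4 and 40.1, also in the line expressing Trib1 alone. Where these probes lie relative to the introduced sequences is not given in the sources used here, so they did not check the labels. Spi1 was at 572 ± 15.6 in the Trib1 line (SD, n = 4), 259.7 ± 25.9 in TB13 and 438 ± 5.58 in TB14. Cebpa, which encodes C/EBPalpha, was at 1388 ± 21.2, 1025 ± 68.7 and 1160.4 ± 13.6 in the same order.

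The TB13 arrays stood apart from the other 8, also in hybridization controls, which do not depend on the cells. The 18 hybridization control probe sets, which report transcripts that the platform's protocol adds to each sample, had a median log2 change of -0.93 in TB13 against Trib1, and 17 of them were lower. In TB14 their median change was 0.0010. The brightest nonspecific control, with 25 G and C bases, read 529.9 on the TB13 arrays against 195.8 in Trib1 and 196.7 in TB14. The upper quartile of all probe sets was 71.8 to 72.5 on the TB13 arrays and 102 to 108.7 on the others. Over the genes tested the median log2 change was -0.39 in TB13 and -0.0022 in TB14. Quantile scaling put the TB13 median at 0.026, and calibration on the hybridization controls at 0.51. Log2 changes and list calls in TB13 alone are therefore given as deposited and after quantile scaling. Of 73 genes named for both lines together, 72 had the same direction and call after quantile scaling, the exception being Trib1. Their sizes did depend on the scaling and are given as deposited unless stated. Quantile scaling moved the log2 change over both lines from -1.87 to -1.44 for Asb2 and from -0.96 to -0.61 for Ctsl. For Mpo it moved from 2.57 to 2.92.

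**Figure D1:**
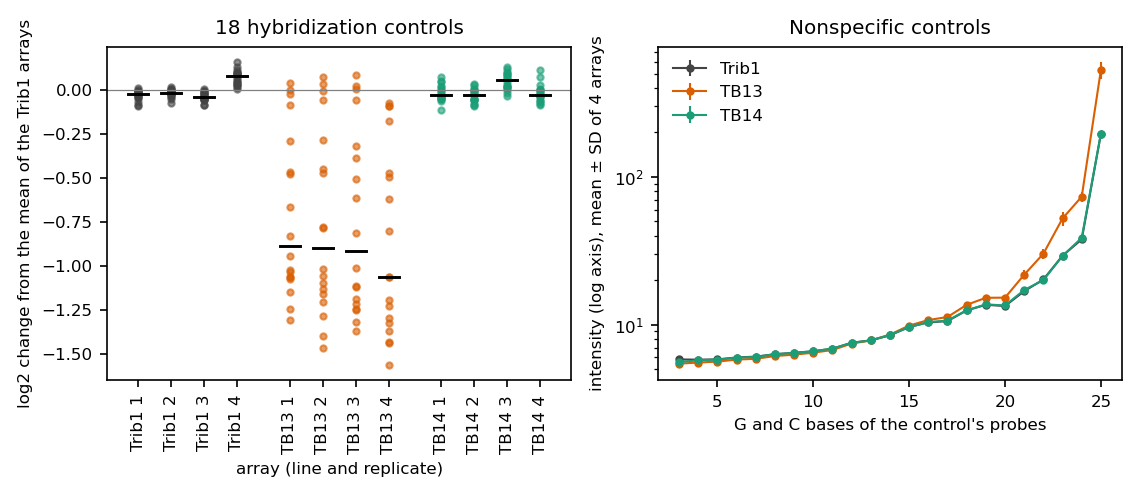
Left, log2 change of each of the 18 hybridization controls from its mean on the Trib1 arrays, on the scale of intensity plus the pseudocount, with 1 column of points per array and a bar at the median. Right, intensity on a log axis of the nonspecific controls against the number of G and C bases of their probes, as mean ± SD of 4 arrays per line. The TB13 points lie lower on the left, and on the right TB13 reaches 529.9 at 25 G and C bases where Trib1 reads 195.8.

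The first comparison set both Bcl11a lines, weighted equally, against the Trib1 line, which is the contrast the series' design names. The genes chosen in connection with the study fell in both lines. Asb2, a subunit of a ubiquitin ligase, went from 384 ± 18.1 (SD, n = 4) to 120.2 ± 8.08 in TB13 and 75.6 ± 3.05 in TB14. Clec5a, a C-type lectin receptor of myeloid cells, went from 621 ± 23.3 to 75.7 ± 6.36 and 149 ± 3.46, and Fcgr3, a low-affinity receptor for immunoglobulin G, from 1526 ± 34.5 to 555 ± 48.5 and 841 ± 11.3. Their log2 changes over both lines were -1.87 ± 0.045, -2.41 ± 0.043 and -1.15 ± 0.036 (± SE), and all 3 passed limma with Benjamini-Hochberg adjustment (adjusted p = 1.7e-17, 3.0e-19 and 1.1e-15). These SEs and p-values, and those for both lines in the next paragraphs, held only the spread between arrays of a line. The difference between TB13 and TB14 did not enter them. Being the study's own choice, these genes are not independent evidence of a direction. Spi1 itself fell by 0.74 as deposited and by 0.40 after quantile scaling on the log2 scale, and Cebpa by 0.34 and 0.19.

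The largest falls shared by both lines were in genes with varied known functions. Avil, an actin-binding protein, stood at 1778 ± 28.4 in Trib1, 178 ± 13.5 in TB13 and 73.9 ± 2.13 in TB14 (SD, n = 4), a log2 change of -3.80 ± 0.039 (SE; limma adjusted p = 2.5e-22). Gzma, a serine protease of cytotoxic granules, had a log2 change of -3.77, and Rnf128, a ubiquitin ligase, of -3.49. F13a1, the A subunit of coagulation factor XIII and a monocyte gene, changed by -3.46, and Tgm2, transglutaminase 2, by -3.37. Pkd2l1, Xlr4b, Cd7, Cyp4f18 and Hgfac completed the 10 largest, with log2 changes from -2.92 to -2.58. Xlr4b fell mainly in TB14, where it read 11.3 ± 0.177 against 459.7 ± 23.0 in TB13, and belongs to a family of near-identical copies, which makes its identity uncertain. The fallen values of Gzma and F13a1 in both lines lay below the array medians, so the size of their change depends on the pseudocount.

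Among the largest shared rises was Mpo, myeloperoxidase of the primary granules of neutrophil precursors. It went from 226 ± 12.5 in Trib1 to 853 ± 10.1 in TB13 and 2296 ± 23.9 in TB14 (SD, n = 4), a log2 change of 2.57 ± 0.027 (SE; limma adjusted p = 2.5e-22). Elane, neutrophil elastase, went from 55.6 ± 2.39 to 109 ± 12.3 and 436 ± 20.4. Fundc1, a receptor for mitophagy, rose by 2.84, Cnn3, calponin 3, by 2.72, and Mgst1, a microsomal glutathione transferase, by 2.20, of which TB13 showed 0.48 as deposited and 0.31 after quantile scaling, and TB14 3.92. The Trib1 values of Cnn3 and Mgst1 lay below the array medians. Ms4a2, the beta chain of the high-affinity receptor for immunoglobulin E, rose by 2.17, Thy1 by 2.11, Marcksl1 by 2.09 and the tetraspanin Cd81 by 1.89. Ugt1a6a and Ugt1a9 rose by 2.86 and 2.00, and because these glucuronosyltransferases share exons they cannot be counted as separate changes. Lat, an adaptor of receptor signalling, rose by 1.79 and Sox4, a transcription factor of progenitors, by 0.85.

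**Figure D2:**
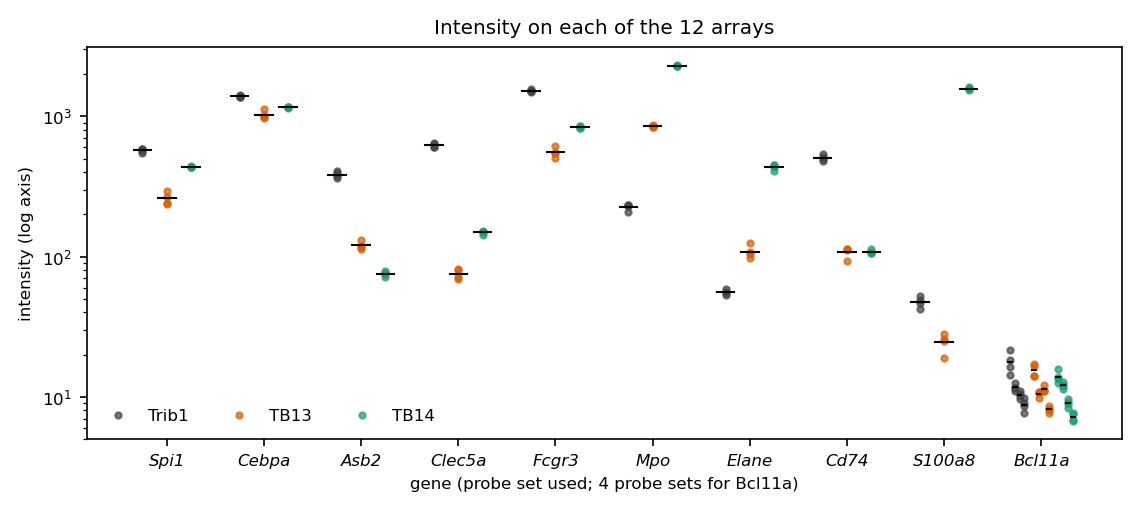
Intensity on a log axis for 10 genes on each of the 12 arrays, with points for arrays, colours for lines and bars at the means. Asb2, Clec5a, Fcgr3 and Cd74 sit lower in both Bcl11a lines, Mpo and Elane higher, S100a8 is high in TB14 alone, and the 4 Bcl11a probe sets stay at or under 21.5 in every line.

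Of the lists fixed before the data were examined, 29 held enough tested genes, and camera, with its preset correlation of 0.01, called 7 shifted over both lines, 2 up and 5 down. With an estimated correlation 2 of these held, primary granule genes (adjusted p = 1.18e-05, and 0.00831 with an estimated correlation) and cholesterol synthesis genes (adjusted p = 2.37e-05, and 0.00831 with an estimated correlation). Of 14 primary granule genes 10 rose and 2 fell over both lines together, also when adjusted over the list alone. TB13 by itself gave 6 rises and 5 falls as deposited, 8 and 4 after quantile scaling, and no call (adjusted p = 0.0935 and 0.141). Mpo, Elane and Nkg7 led the rises over both lines, the last with a log2 change of 0.68. Ctsg, Prtn3, Gstm1 and Igsf6 were called in opposite directions in TB13 and TB14 as deposited. Among 18 cholesterol synthesis genes 17 fell and none rose, both over all genes and adjusted over the list alone. The fall was larger in TB13, with a median log2 change of -1.42 as deposited and -0.84 after quantile scaling, than in TB14, with -0.17 and -0.19. As deposited 16 of the genes fell 2-fold or more in TB13 and none in TB14, where 9 fell and 2 rose. Lss, lanosterol synthase, changed by -1.44, Fdft1, squalene synthase, by -1.04 and Insig1, a sterol-regulated membrane protein, by -1.02 over both lines, but by -0.55, -0.29 and -0.17 in TB14. Sc5d changed by -0.94 over both lines and -0.14 in TB14, while 1 of its 2 other probe sets read 0.054 over both lines and did not pass (limma adjusted p = 0.286).

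The other lists called down lost the call with an estimated correlation, and with a stricter filter those of study, adhesion and BCL2 family genes and the stromal list did too (adjusted p = 0.0611 for each). For the 3 study genes, which the study chose, the adjusted p was 0.0285 and then 0.135 with an estimated correlation. Of 16 phagocyte oxidase and lysosome genes 15 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.000357, and 0.135 with an estimated correlation). Hexa, Ncf4, Ctsl and Ctss had log2 changes of -1.33, -1.17, -0.96 and -1.78. Among 17 adhesion and migration genes 14 fell and 1 rose, also adjusted over the list alone, and Itgam, Cd44 and Itgax changed by -1.65, -1.50 and -1.50 (adjusted p = 0.0244, and 0.112 with an estimated correlation). Of 13 BCL2 family genes 12 fell and 1 rose, also adjusted over the list alone, although the list's median turned to 0.049 under calibration on the controls, with the BH3-only genes Pmaip1 and Bid at -0.99 and -0.88 (adjusted p = 0.0275, 0.261 with an estimated correlation, and 0.0824 against matched random lists). The stromal and endothelial list was called up (adjusted p = 0.0482, and 0.146 with an estimated correlation), with 7 of 9 members higher, also adjusted over the list alone, but not after quantile scaling (adjusted p = 0.199) or against matched random lists (adjusted p = 0.276). Without the 4 TB13 arrays that list turned to the other direction (adjusted p = 0.918), and it lost its call without Trib1 replicate 1 (0.0522), Trib1 replicate 2 (0.0506), TB13 replicate 1 (0.0512) or TB14 replicate 2 (0.0505).

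Among lists that did not pass over both lines as deposited, monocyte and macrophage genes gave 8 rises and 8 falls of 18, with a median of 0.044 and a mean of -0.54 (camera adjusted p = 0.946), and secondary granule and mature neutrophil genes 10 rises and 7 falls of 18 (adjusted p = 0.0727), in both cases also adjusted over the list alone. The monocyte genes Adgre1, Ccl6, Ccr2, Cd68, Csf1r, Ctss, F13a1 and Lgals3, at 154.8 to 3269 in Trib1, read lower in each Bcl11a line. Lyz2 and Ccl9 were at 406.6 and 3427 in Trib1, and Lyz2 rose in TB14. The remaining monocyte genes were dim, at 20.3 to 48.0 in Trib1, and all read higher in TB13 as deposited. Of 13 dendritic cell and MHC class II genes 9 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0651, and 0.000217 after quantile scaling), or 8 and 5 under calibration on the controls. In TB13 alone 8 fell and 4 rose as deposited, 8 and 3 after quantile scaling, and the list was not called (adjusted p = 0.72 and 0.141). The class II genes H2-DMa, H2-Aa and H2-Ab1 and the invariant chain gene Cd74 had log2 changes of -2.40, -2.04, -1.90 and -2.11. A dimmer second probe set of H2-DMa read -0.45, at 45.2 in Trib1, 42.7 in TB13 and 19.7 in TB14. Of 28 PU.1 target genes of myeloid cells 18 fell and 7 rose, also adjusted over the list alone (adjusted p = 0.115, and 0.00106 after quantile scaling), or 15 and 13 under calibration on the controls, with Cd68 at -1.90 and Csf1r, the receptor for macrophage colony-stimulating factor, at -1.23. Among transcription factor genes Id2, Egr1 and Jun changed by -2.31, -2.00 and -1.54 and Gfi1 by 0.97, with a dimmer probe set of Jun at -0.41. Their list of 26 split into 10 rises and 12 falls, also adjusted over the list alone, with a median of -0.053 while camera pointed up (adjusted p = 0.623). Other large falls were in Cdkn2a, the locus of cell cycle inhibitors, at -2.44, in the interleukin-1 decoy receptor gene Il1r2 at -2.55, in the ERK phosphatase gene Dusp6 at -1.70 and in the chemokine gene Ccl3 at -1.96.

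Over both lines 9447 genes passed limma, 3181 higher and 6266 lower than in Trib1, and 383 of them changed 2-fold or more, 46 up and 337 down. After quantile scaling the split was 4332 higher and 3538 lower, and calibration on the hybridization controls gave 7859 and 1457. Changes of 2-fold or more were 58 up and 185 down after quantile scaling and 249 up and 105 down under that calibration, and as deposited 6032 genes rose and 6356 fell without a filter and 880 and 5234 with the stricter one, so the balance of rises and falls rested on the scaling and the filter. With the 4 TB13 arrays left out 6925 genes were called, and with each line's mean as 1 sample 9.

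The second comparison set TB14 alone against Trib1, on arrays whose hybridization controls differed by a median of 0.0010. S100a8 and S100a9, calcium-binding proteins of neutrophils and monocytes, rose from 47.7 ± 4.28 to 1569.8 ± 33.4 and from 166 ± 10.5 to 2570.3 ± 72.0 (SD, n = 4), log2 changes of 4.71 ± 0.068 and 3.85 ± 0.063 (SE; limma adjusted p = 1.9e-20 and 1.1e-19). Mgst1 rose by 3.92 and Mpo by 3.28, Gfi1, a repressor of granulocyte precursors, by 1.75, and Lyz2, lysozyme, by 1.43. Avil fell with a log2 change of -4.37. Xlr4b went from 755 ± 16.8 to 11.3 ± 0.177, and Gzma and F13a1 had log2 changes of -3.92 and -3.58, with the TB14 values of all 3 below the array medians, so the sizes depend on the pseudocount.

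In TB14 camera called 18 of the 29 lists, 5 up and 13 down, and 15 held with an estimated correlation. Of 14 primary granule genes 11 rose and 1 fell, also adjusted over the list alone (median log2 change 0.64, adjusted p = 3.6e-08). Cell cycle genes rose in 27 of 33 cases and fell in 2, also adjusted over the list alone, by a small median of 0.25 (adjusted p = 6.81e-08), with the mitotic kinases Aurka and Aurkb at 0.38 and 0.28. Of 20 glycolysis and hypoxia genes 15 rose and 4 fell, with 16 rises adjusted over the list alone (adjusted p = 2.68e-05). Pfkl, a phosphofructokinase, and Slc2a1, a glucose transporter, rose by 1.38 and 0.39. MYC target and ribosome biogenesis genes rose in 15 of 23 cases, 16 adjusted over the list alone, and fell in 1 (adjusted p = 0.000123), a call that ended against matched random lists (adjusted p = 0.113), with the base excision repair gene Apex1 at 0.28. Genes of corepressors and chromatin complexes linked to BCL11A rose in 16 of 21 cases, also adjusted over the list alone, and none fell (adjusted p = 0.000197).

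The lists called down in TB14 included myeloid receptor and antigen presentation genes. Of 13 dendritic cell and MHC class II genes 9 fell and none rose, also adjusted over the list alone, with a median of -1.71 (adjusted p = 3.6e-08). H2-Aa changed by -2.40, H2-Ab1 by -2.13 and Cd74 by -2.10. Of 28 PU.1 targets 17 fell and 6 rose, 7 adjusted over the list alone (adjusted p = 7.26e-05), and the 3 study genes had the same adjusted p. Fc and lectin receptor genes fell in 10 of 19 cases and rose in 4, with 11 falls adjusted over the list alone (adjusted p = 0.000629), and Cd300lf and Cd300a, inhibitory receptors of myeloid cells, changed by -2.29 and -2.10. Among 18 interferon response genes 11 fell and 1 rose, 2 adjusted over the list alone (adjusted p = 0.00011), with Usp18 at -1.97 and the immunoproteasome gene Psmb9 at -0.89. Of the 2 other Psmb9 probe sets 1 read -0.038 over both lines and did not pass. Of 15 inflammatory cytokine and chemokine genes 13 fell and 1 rose, also adjusted over the list alone (adjusted p = 1.23e-05), with Il1rn, the interleukin-1 receptor antagonist, at -2.03 and Ccl6 at -1.05. A dimmer other probe set of Cd300a changed less, with -0.37 over both lines. Of the 2 other Il1rn probe sets the dimmer read -0.55 and the brighter -2.95 over both lines, against -1.77 for the one used. Phagocyte oxidase and lysosome genes fell in 13 of 16 cases and rose in 2, also adjusted over the list alone (adjusted p = 8.17e-06), and adhesion and migration genes fell in 10 of 17 and rose in 3, 4 adjusted over the list alone (adjusted p = 0.000296). Cholesterol synthesis genes fell in 9 of 18 cases, 12 adjusted over the list alone, and rose in 2, by a small median of -0.17 (adjusted p = 0.00985, and 0.0593 under calibration on the controls). Monocyte and macrophage genes moved both ways, 9 of 18 down and 3 up, 4 adjusted over the list alone (adjusted p = 0.00406).

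The calls for 3 further lists ended with an estimated correlation, BCL2 family genes (adjusted p = 0.0916 with an estimated correlation), ERK feedback and immediate early genes (adjusted p = 0.0983 with an estimated correlation) and cytokine, STAT5 and STAT3 response genes (adjusted p = 0.0784 with an estimated correlation). In the last of these Pim2, a STAT5-induced kinase gene, changed by -1.67 and Socs3 by -1.56. In total 5446 genes were called in TB14, 3034 up and 2412 down, and 311 changed 2-fold or more, 114 up and 197 down. Under each of 5 scalings 88 genes rose and 176 fell 2-fold or more.

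**Figure D3:**
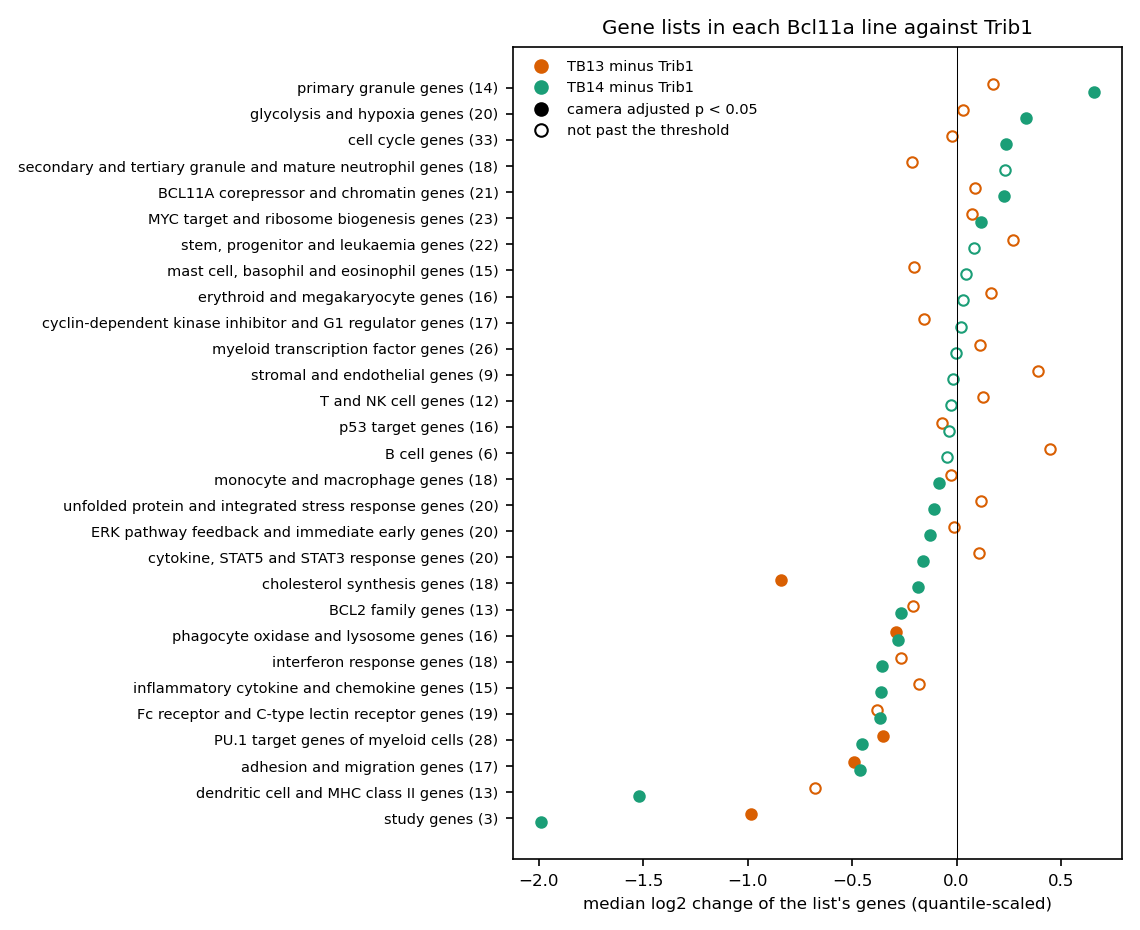
Median log2 change of the tested genes of each of the 29 lists, with the number tested in brackets, for TB13 and TB14 against Trib1 after quantile scaling. Filled points passed camera at an adjusted p under 0.05 and open points did not. Primary granule genes lie highest in TB14, at a median of 0.66, and cholesterol synthesis genes lie lower in TB13, at -0.84, than in TB14, at -0.19.

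The third comparison set TB13 against Trib1 and carries the difference between arrays described for the controls. Cholesterol synthesis genes were lower in 17 of 18 cases, also adjusted over the list alone, with a median log2 change of -1.42 as deposited and -0.84 after quantile scaling (adjusted p = 0.00119, 0.0472 with an estimated correlation, and 1.46e-07 after quantile scaling). Cdkn2a changed by -3.34 and -2.93 in the same 2 settings, and Alox5, 5-lipoxygenase, by -3.75 and -3.22. Itgam, the alpha chain of the integrin Mac-1, changed by -2.59 and -2.43. Clec5a changed by -2.85 and -2.29, Mpo by 1.86 and 2.38, and Mmp8, neutrophil collagenase, by 1.42 and 2.04.

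All 16 phagocyte oxidase and lysosome genes were lower in TB13 as deposited, also adjusted over the list alone (adjusted p = 0.00363, 0.17 with an estimated correlation, and 0.112 against matched random lists), and 14 after quantile scaling (adjusted p = 0.000105). Cell cycle genes were lower in 32 of 33 cases as deposited, also adjusted over the list alone (adjusted p = 0.00361, and 0.128 with an estimated correlation). After quantile scaling 10 of them were higher and 16 lower (adjusted p = 0.364), and under calibration on the controls their median was 0.12, so this list gave no direction. The stromal and endothelial list was called up in TB13 (adjusted p = 0.0274, and 0.132 with an estimated correlation), with 7 of 9 members higher, also adjusted over the list alone, but not after quantile scaling (adjusted p = 0.172). The lists of study genes, PU.1 targets and adhesion and migration genes were not called in TB13 as deposited (adjusted p = 0.103, 0.211 and 0.0514) and were called down after quantile scaling (adjusted p = 0.0306, 0.0272 and 0.0331). Of the 28 PU.1 targets 21 fell and 5 rose as deposited and 17 and 7 after quantile scaling, but 12 fell and 14 rose under calibration on the controls. As deposited 10388 genes were called in TB13, 3257 up and 7131 down, or 7676 and 7247 without a filter. Quantile scaling gave 4714 up and 4291 down, and calibration on the hybridization controls 8240 up and 1323 down. Changes of 2-fold or more were 113 up and 1639 down as deposited, 566 up and 425 down after quantile scaling, and 3900 up and 59 down under calibration on the controls.

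The fourth comparison asked which genes changed the same way in both Bcl11a lines. Under each of 5 scalings 14 genes rose and 45 fell by 2-fold or more in both lines. The rises included Mpo, Ms4a2, Thy1, Lat, Cd81, Marcksl1, Cnn3 and Fundc1, and the falls Avil, Gzma, Rnf128, F13a1, Tgm2, Clec5a, Cd74, Cd68, Ctss, Id2, Egr1, Dusp6 and Cdkn2a. As deposited 2477 genes were called the same way, 365 up and 2112 down, after quantile scaling 2703, 1105 up and 1598 down, and under calibration on the controls 2759, 2027 up and 732 down. In the other direction 2592 genes were called opposite ways as deposited and 1294 after quantile scaling. Independent lists of the same sizes would share 880.5 rises and 1532.6 falls as deposited, and 1084.1 and 891.6 after quantile scaling. At 2-fold or more 20 rises and 170 falls were shared as deposited, where independent lists would share 1.1 and 28.8. Quantile scaling gave 35 rises and 111 falls, and calibration on the controls 81 rises and 48 falls.

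Both lines were compared with the same 4 Trib1 arrays. In 100 simulations of unchanged groups against shared controls no gene was called the same way in both, and the log2 changes correlated across genes at 0.50. The observed correlation across genes, which are not independent replicates, was 0.30 as deposited and 0.36 after quantile scaling. The observed covariance was 0.073 against a simulated 0.00145, a difference of 0.071. With the Trib1 arrays split into 2 and 2, one pair for each line, the 6 splits gave 2055 to 2161 genes called the same way and a covariance of 0.068 to 0.076. The simulations and the splits held only the spread between arrays of a line. Neither could show a peculiarity of the single Trib1 line, which both comparisons would share.

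**Figure D4:**
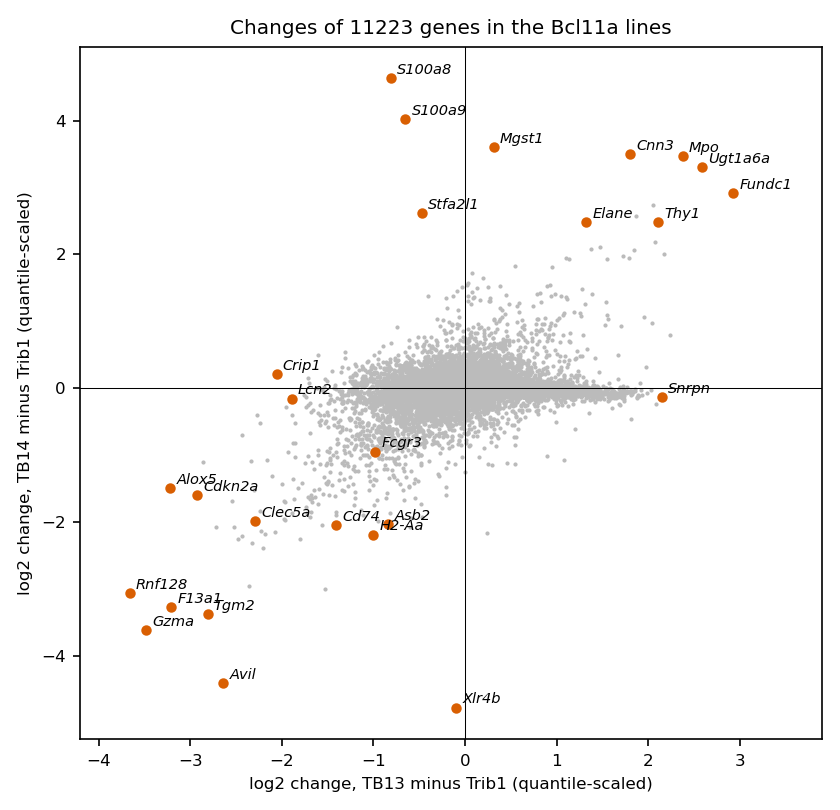
Log2 change of each of the 11223 genes in TB14 against Trib1, vertical, and in TB13 against Trib1, horizontal, after quantile scaling, with named genes marked. Avil, Gzma and Rnf128 lie low on both axes and Mpo high on both, while S100a8 lies at 4.63 in TB14 and -0.81 in TB13, a TB13 value that turned to 0.50 under calibration on the controls.

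The last comparison set TB14 against TB13. S100a8 was at 1569.8 ± 33.4 in TB14 and 24.5 ± 3.9 in TB13 (SD, n = 4), a log2 difference of 5.42 ± 0.068 (SE; limma adjusted p = 4.6e-21), and S100a9 differed by 5.00. The TB13 mean of S100a8 lay below the TB13 array medians of 25.5 to 25.9, as did that of Stfa2l1, so the size of these differences depends on the pseudocount. Mgst1, Stfa2l1, Crip1, Alox5, Ptgr1 and Lcn2, lipocalin 2, were also higher in TB14, by 3.44, 3.25, 2.92, 2.41, 2.29 and 2.23. Lower in TB14 were Xlr4b at -4.30, Tcl1b3 at -1.90, Snrpn at -1.79, Cox6a2 at -1.78, Aif1l at -1.64 and Ddit3, a transcription factor of the stress response, at -1.51. Fahd2a and Aplp2 were lower by the probe set used, at -1.64 and -1.55, but 3 of 3 other Fahd2a probe sets read 0.29 to 0.58 higher in TB14 and 3 of 4 other Aplp2 probe sets 0.81 to 1.04 higher.

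Cholesterol synthesis genes were higher in TB14 than in TB13 in 17 of 18 cases, also adjusted over the list alone (median 1.33 as deposited and 0.76 after quantile scaling; camera adjusted p = 0.00127, and 0.0254 with an estimated correlation). Cell cycle genes were higher in 32 of 33 cases, also adjusted over the list alone (median 0.83 and 0.28; adjusted p = 0.000175, and 0.0254 with an estimated correlation). Dendritic cell and MHC class II genes were lower in 10 of 13 cases and higher in 1, also adjusted over the list alone (adjusted p = 0.000565, and 0.0254 with an estimated correlation). Camera called 11 lists, 7 up and 4 down, of which 3 held with an estimated correlation and 4 were called under all 5 scalings. The other 8 had adjusted p from 0.0527 to 0.271 with an estimated correlation. In all 10405 genes differed, 7108 higher and 3297 lower in TB14, against 7245 and 7770 without a filter, 4362 and 4615 after quantile scaling and 1515 and 7938 after calibration on the hybridization controls. Differences of 2-fold or more under each of the 5 scalings numbered 16 up and 40 down.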

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

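The tests of the 3 patterns weighed here were chosen after the results were seen, and so were cyclic loess scaling and calibration on the hybridization controls.

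Most of the 11223 genes tested read lower on the TB13 arrays, with a median log2 change of -0.39, whereas without the filter on dim probe sets 7676 genes rose and 7247 fell. The nonspecific control with the brightest signal, which no comparison used, stood out on the same arrays at 529.9 against 195.8 in Trib1 and 196.7 in TB14. The tables argue against an effect of Bcl11a that both lines share, since the TB14 median was -0.00219. Genes within the range of the hybridization controls had a median of 0.225 after calibration on those controls. That set left out genes below the lowest control in TB13, which can raise its median. In the brightest quintile of all genes the calibrated median was 0.084 and in the next 0.167, which argues against less RNA from TB13 cells for these genes only. The 24 poly-A control probe sets were all lower in TB13, with a median log2 change of -0.43. A lower response of the TB13 arrays may account for the shift, as the hybridization controls themselves moved by a median of -0.928. Why these arrays responded less was not tested, and array batch and line cannot be separated because all 4 arrays of the line were affected.

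Among dim probe sets, most read higher on the TB13 arrays. Genes of receptor, keratin-associated, defensin and crystallin families, few of which a myeloid cell would be thought to express, rose in 85.5% of 221 cases, which is 189 genes. Of 8753 other genes below a cutoff set above the families' median intensity, 73.5% rose. The sets were not matched on intensity, so intensity alone could give the difference between these shares. In TB14 3 of the 221 rose. So many rises in those families argue against true changes of transcripts as the whole cause, and nonspecific signal may account for them. True rises of single dim genes stay open.

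Study, phagocyte and MHC class II lists were called down in TB14, while in TB13 as deposited the study list (3 of 3 fell, camera adjusted p = 0.103, and 0.0306 after quantile scaling) and the MHC class II list (8 of 13 fell, adjusted p = 0.72, and 0.141 after quantile scaling) were not called and the phagocyte list (16 of 16 fell, adjusted p = 0.00363) lost its call with an estimated correlation (adjusted p = 0.17). The tables argue against the response of the arrays as the whole cause in TB14. There the 3 lists had a median of -0.516 and the hybridization controls a median of 0.0010. They argue the same for study and phagocyte genes in TB13. Calibration on those controls shrank the medians of these lists from -1.58 and -0.65 to -0.854 and -0.208, which were still negative. For the MHC class II list in TB13, which also holds dendritic cell genes, that cause stays open. Its median turned from -0.74 to 0.372 with that calibration but stayed at -0.68 after quantile scaling. The median did not describe every gene, since of the 13 genes 6 fell and 2 rose in TB13 under every scaling used. The invariant chain gene Cd74 changed by -2.11 as deposited and by -1.10 with that calibration. Fewer monocytic cells may contribute and stay undecided, since leukaemia cells can express the same genes. Of 18 monocyte and macrophage genes 3 rose and 9 fell in TB14. Among the 8 brightest of them in Trib1, at 406.6 or more, 7 fell and 1 rose in TB14. The rise was Lyz2 at 1.43, and the falls included Ctss at -1.38, Ccl6 at -1.05 and Ccl9 at only -0.038. Mpeg1 and Ms4a6c, at 0.83 and 0.47 in TB14, read only 30.2 and 38.1 in Trib1. An effect of Bcl11a, which the design names, and a difference between single lines unrelated to it cannot be told apart with 1 Trib1 line.

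In 12 of 285 groups of 4 arrays tested for named genes 1 array lay far from the others, where chance gives about 1 in 20 or 14.2. Intensities were 157.7 for Avil on TB13 replicate 4, 94.34 for Cyp4f18 on TB13 replicate 1, 40.29 and 424.5 for Marcksl1 on Trib1 replicate 2 and TB14 replicate 2, and 54.8 for H2-DMa on TB13 replicate 4. They were 93.37 for Cd74 on TB13 replicate 2, 769.2 and 50.44 for Cdkn2a on Trib1 replicate 3 and TB13 replicate 4, and 32.29 and 151.7 for Gfi1 on Trib1 replicate 2 and TB14 replicate 1. Dusp6 read 557.5 on Trib1 replicate 3 and Itgax 253.7 on Trib1 replicate 1. The trimmed mean of TB13 replicate 4 was 80.94, where the other TB13 arrays had 82.66 to 82.95.

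Some genes changed in opposite directions in TB13 and TB14 as deposited, with the difference itself tested. TB14 minus TB13 was -1.896 for Tcl1b3, -1.79 for Snrpn, -1.644 for Fahd2a, -1.512 for Ddit3 and -1.262 for Trib3, which were higher in TB13 than in Trib1. For Fahd2a this rests on 1 probe set, as 3 of 3 others read lower in TB13 than in Trib1, the dimmest 22.2 against 89.5. It was 5.418 for S100a8, 4.999 for S100a9, 3.246 for Stfa2l1, 2.924 for Crip1, 2.292 for Ptgr1 and 1.782 for Slc2a1, which were lower in TB13 than in Trib1. Under calibration on the hybridization controls the TB13 change of S100a8 turned to 0.50 and that of Stfa2l1 to 0.89. Over all genes 2592 were called in opposite directions as deposited, and 919 in that way both as deposited and after quantile scaling. Of the 919, 0 changed by 2-fold in each line in both of these settings at once. The lists of cell cycle genes and of glycolysis and hypoxia genes also differed between the lines (camera adjusted p = 0.000175 and 0.013). With an estimated correlation the first held (adjusted p = 0.0254) and the second did not (adjusted p = 0.162).

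Probe sets without a gene name, which no comparison used, also held changes. Of 6061 tested, 75 changed by 2-fold or more in the same direction in both Bcl11a lines, 6 up and 69 down.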

How the results depend on the processing

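Cyclic loess scaling, calibration on the hybridization controls, quantile scaling joined with 2-fold or with line means, and leaving out TB13 were chosen after the data were seen. Counts of genes called stayed within 1.5 times the reported ones under every alternative except those given next. The stricter filter, which tests fewer genes, gave 6585 for TB13, 6114 for both lines and 6586 for TB14 against TB13. A threshold of 2-fold gave 1752 for TB13, 311 for TB14, 383 for both lines, 1830 for TB14 against TB13 and 190 the same way, and with quantile scaling 991, 277, 243, 926 and 146. With each line as 1 sample, which leaves fewer samples, 9 genes were called (100 at an unadjusted p under 0.05), and 106 after quantile scaling. Lists shifted over both lines numbered 13 with quantile scaling, 14 with cyclic loess, 14 with calibration on controls, 15 without a filter, 2 with an estimated correlation, 12 with line means, 18 without TB13 and 14 against matched random lists. The stricter filter gave 9, 6 up and 3 down, and ended 4 of the 7 calls, those of study, BCL2 family, adhesion and stromal genes. The cause of the changes in list counts was not tested. Leaving out 1 array gave 10253 to 10371 genes for TB13, 5005 to 5118 for TB14, 9085 to 9528 for both lines, 2288 to 2639 the same way, 10280 to 10389 for TB14 against TB13, and 6 to 8 lists.

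Replicate numbers did not pair the arrays: after removing line means, arrays with the same number correlated at -0.105 to 0.12, and 3 of 12 fitted their own number best. With the number as a block 10373, 5378, 9420, 10382 and 2451 genes and 6 lists were called.

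Reversals were few among the checks made, and their cause was not tested. For single genes these checks left out TB13 against Trib1, and for lists they covered both lines together only. In TB13 against Trib1 the changes of S100a8 and Stfa2l1 and the median of the MHC class II list turned over under calibration on the controls. The stromal and endothelial list turned over without TB13 (adjusted p = 0.918). For TB14 against TB13, Aplp2 read 0.25 as the mean of its probe sets and 1.04, 0.81 and 1.02 on others, and Fahd2a 0.58, 0.37 and 0.29 on others. Sc5d read 0.054 over both lines on another probe set. Of the checks on named genes over both lines 1889 kept direction and call and 112 lost the call, 71 of these with line means and 37 with line means after quantile scaling. Signal over background limits Bcl11a and Trib1, whose probe sets stayed dim.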

Other observations

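The tests on other divisions of the arrays were planned, and the comparison of each line with the other lines was made after the data were seen.

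Genes of other blood lineages also differed between the lines. Fcer1a, the alpha chain of the high-affinity receptor for immunoglobulin E, read 482 ± 14.5 in Trib1, 244 ± 18.5 in TB13 and 149.5 ± 2.58 in TB14 (SD, n = 4), while Ms4a2, the beta chain of the same receptor, rose. Siglecf, a receptor of eosinophils, had a log2 change of -1.02 over both lines and Cma1, a mast cell chymase, of -1.17, and their list of mast cell, basophil and eosinophil genes held 4 rises and 9 falls among 15, also adjusted over the list alone (camera adjusted p = 0.623). Car2, carbonic anhydrase 2, went from 277 to 55.1 and 53.2, and Hba-a1, a globin gene, rose by 0.79. Their erythroid and megakaryocyte list did not pass (adjusted p = 0.052).

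In the list of unfolded protein and integrated stress response genes Ddit3 and Trib3 fell in TB14 by 1.08 and 0.99 on the log2 scale against Trib1 and rose in TB13 by 0.43 and 0.27 as deposited and by 1.08 and 0.89 after quantile scaling. That list held 4 rises and 11 falls among 20 in TB14, also adjusted over the list alone (camera adjusted p = 0.0526). Angpt1, a ligand of the receptor Tie2, rose by 1.11 in TB14.

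Each line was also set against the other lines in the same way. Genes called numbered 9447 for Trib1, 10528 for TB13 and 9846 for TB14, and genes changed 2-fold or more against each of the other lines in the same direction 190, 1063 and 75. After quantile scaling the last set was 146, 662 and 62. Total counts of genes called were thus not particular to the line without Bcl11a. Camera called 7 lists for Trib1, 10 for TB13 and 16 for TB14, and 13, 4 and 19 after quantile scaling. Counts of lists were therefore not particular to that line either. The set changed 2-fold or more was larger only for TB13, whose arrays responded less, and smaller for TB14 than for Trib1.

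Other divisions of the same arrays into groups of the same sizes were counted, the real one included. For genes called in TB13 against Trib1 1 of 35 gave as many (10388, highest other 0), for TB14 against Trib1 1 of 35 (5446, highest other 0) and for TB14 against TB13 1 of 35 (10405, highest other 0). For both lines 1 of 100 drawn divisions gave as many (9447, highest other 345). For genes called the same way it was 1 of 100 (2477, highest other 0). Divisions that mix lines put the difference between lines into the spread, so low gene counts there were to be awaited. Arrays of a line were nearly alike, so these counts say nothing about chance differences between single lines. For the numbers of lists shifted the divisions could not decide, since uneven mixes of lines still carry part of the difference between them. As many came from 60 of 100 divisions for both lines (7, highest other 18), from 13 of 35 for TB13 (4, highest other 6), from 2 of 35 for TB14 (18, highest other 18) and from 7 of 35 for TB14 against TB13 (11, highest other 13).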
